A study of Tetrahymena thermophila with 4 samples.

How the data were processed

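Med31-FZZ tagged Tetrahymena thermophila cells were grown at 30 °C and 100 rpm in SPP medium, a rich broth. Nuclei were sonicated, the cleared lysate was incubated with anti-FLAG M2 gel, and libraries were made with a TruSeq ChIP kit, per the labels' protocols. There were 2 sets of cells with 1 input and 1 IP library each, 4 libraries in all. The labels do not say whether the sets came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

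The authors deposited 4 tables of whole-number read counts, 1 per set for ORFs and 1 per set for intergenic regions, and per the file headers each holds an input and an IP column. No normalization is recorded, and the values are raw counts. FastQC, BWA and SAMtools were used per the submitters' processing notes. Aligner settings, genome build, treatment of duplicate and multiply mapped reads, and the counting rule are not given in the sources used here. If reads from near-identical genes were placed at random or dropped, counts of multigene families such as surface antigens, histones or ubiquitin would be uncertain, and duplicates kept in the counts would raise the spread between IPs. All 26996 ORF identifiers matched locus tags of the RefSeq annotation JCVI-TTA1-2.2. That annotation gave no symbols, so product names come from the deposited tables. Coordinates are those of the deposited tables.

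IP was compared with input by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) with Benjamini-Hochberg adjustment over the ORFs or the intergenic regions tested. Library size was the sum of ORF and intergenic counts, times a trimmed-mean (TMM) factor over all features. The factors were 0.755 and 0.765 for the inputs of sets 1 and 2, and 1.12 and 1.54 for the IPs. Low counts were removed with filterByExpr, and the test had 2 residual degrees of freedom. CPM uses the scaled library sizes. A fold for a feature without reads in both IPs is a lower bound for counting error only, from a floor of 3 reads in each IP library on the scaled library sizes. On library totals the bounds of the 23 named features without IP reads were 0.596 to 0.600 times as large.

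Log2 IP/input ratios per set used a pseudocount of 0.5 reads. The 1.5-fold rule asked for 20 reads in each input. The ORF share was tested by exact permutation. Gene lists were regular expressions on product names: 23 lists, of which 22 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, then with an estimated correlation, and with fry. With an estimated correlation camera tests on the 2 residual degrees of freedom, while at the preset one the degrees of freedom follow the number of genes. Other tools were DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

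The genes named were fixed by rule before the data were examined, as were the lists, tests and most alternatives. Among ORFs past adjusted p 0.05, with at least 20 reads in each input and the same direction in both sets, the rule took the 10 largest log2 fold changes, the 10 largest with an informative product name, the 5 highest mean IP levels and the 5 most depleted. It also took the 3 largest absolute changes past the threshold in each list called by camera, the 5 most enriched and 3 most depleted intergenic regions, and MED31. This gave 55 ORFs and 8 regions.

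The same test was run on simulated counts with 100 ORFs changed 4-fold and 100 changed 16-fold. With a dispersion of 0.02 in all libraries, 100% of the 4-fold and 100% of the 16-fold changes were recovered, with 7 false calls among 25900 unchanged ORFs. With a dispersion of 0.3 in the IPs, 0% of the 4-fold and 0% of the 16-fold changes were recovered, with 0 false calls among 25875. The dispersion fitted to the real ORF counts was 0.633. The simulation changed few of the 26075 ORFs tested at that setting, while 8207 of 25359 passed in the real data. Benjamini-Hochberg adjustment depends on the share of ORFs that change, so the simulation gives neither the power nor the rate of false calls in the real data.

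The labels tie the input and IP of a set to the same cells, so set numbers were taken as pairing the libraries. The deviations of input and of IP between sets correlated at 0.0164 across ORFs and 0.00354 across intergenic regions. The fit without the block was the main one, and the blocked value, with 1 residual degree of freedom, is printed where it changes a call. Alternatives covered the test, scaling, low-count filter, block, a 1.2-fold threshold, features adjusted together, thresholds of the ratio rule, and each library left out. Added after the data were seen were leaving out the 2 densest scaffolds, leaving out ORFs dense in input from the lists alone or from the lists and the genes they are compared with (the latter also with an estimated correlation), and limiting flanks to regions with names in order.

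The order of names in the intergenic tables was checked by the fewest rows that must be removed to leave scaffold and start order, and 95% intervals of Spearman's rho come from 1000 bootstrap samples. Intergenic positions and lengths were not used for named regions, and a comparison matched on length was set aside for that reason. The planned comparison of intergenic regions by the orientation of their genes was not run, because neither the tables nor the annotation used here give strand.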

Results

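Binding of Med31 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the ciliate Tetrahymena thermophila during vegetative growth. Med31 is a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. The cells carried Med31 with an FZZ tag, which was pulled down with an anti-FLAG gel. There were 2 sets of tagged cells, each with 1 input library (chromatin before pull-down) and 1 immunoprecipitated (IP) library, so n = 2 for input and n = 2 for IP. No untagged strain was analysed here, so the background measured in these data is the input. Reads were counted over 26996 genes, listed as open reading frames (ORFs), and 27780 intergenic regions. The inputs held 19203065 and 18737533 counted reads in sets 1 and 2, and the IPs held 33426436 and 44019803. A count of 0 allowed a level of up to 0.156 and 0.160 CPM of the library total in the inputs of sets 1 and 2, and up to 0.0897 and 0.0682 in the IPs. These floors, and the intervals given here, cover counting error only.

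The comparison of IP with input asks where on the genome tagged Med31 was recovered. The genes most enriched in IP coded for a mixture of membrane proteins, enzymes and proteins of no assigned function. A hypothetical protein gene, TTHERM_001362507 (scaffold scf_8254033, bases 6753 to 7352), had the largest fold change, from 5.10 ± 0.677 CPM in input to 333 ± 7.28 in IP (SD, n = 2), or 65.4-fold. TTHERM_00136300 (scf_8254582, bases 613161 to 613898), named after a 2,3-diketo-5-methylthio-1-phosphopentane phosphatase, was 55.0-fold higher in IP (log2 fold change 5.78, SE 0.32). The alternative oxidase gene TTHERM_00695590, which codes for a mitochondrial terminal oxidase, was 34.0-fold higher (12.3 ± 1.86 CPM in input and 417 ± 114 in IP). A major facilitator (MFS) transporter gene, TTHERM_00245250, was 34.8-fold higher, and the ornithine decarboxylase antizyme gene TTHERM_01193630, whose product restrains polyamine synthesis, was 33.5-fold higher.

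Other genes among the 10 largest changes with an informative product name were of mixed annotation. A nucleotide-sugar transporter gene (TTHERM_00654150) was 34.5-fold higher in IP and an oxysterol-binding protein gene (TTHERM_00568000) was 33.8-fold higher. Genes of the Mpv17/PMP22 family (TTHERM_00726180) and the SPFH domain/band 7 family (TTHERM_00392720) were 37.5-fold and 36.1-fold higher. A UbiE/COQ5 family methyltransferase gene (TTHERM_00616270) was 33.1-fold higher and a gene annotated as inhibitor of apoptosis-promoting Bax1 protein (TTHERM_00760770) was 27.9-fold higher. The remaining genes among the 10 largest changes of any annotation were TTHERM_00490850 (UBA/TS-N domain, 54.2-fold), TTHERM_001080487 (hypothetical, 53.7-fold), TTHERM_00191880 (hypothetical, 51.2-fold), TTHERM_000522989 (hypothetical, 48.4-fold), TTHERM_00059150 (methyltransferase domain, 42.8-fold) and TTHERM_00401850 (integral membrane protein with DUF6, 42.0-fold). The inputs of TTHERM_00191880 differed, with 287 and 93 reads, and its log2 fold change of 5.68 was 6.70 without the input of set 1 and 5.09 without that of set 2. Its call was lost when the IP of set 1 or of set 2 was left out (adjusted p = 0.130 and 0.112).

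By IP level among enriched genes, TPA2 (TTHERM_00700900), which codes for a P-type ATPase that pumps ions across membranes, stood first at 5771 ± 1918 CPM in IP against 357 ± 21.7 in input (SD, n = 2), a 16.2-fold difference. An ABC-2 family transporter gene (TTHERM_00713380) followed at 5504 ± 2269 CPM, 5.12-fold above input. TTU3 (TTHERM_00077240), which codes for polyubiquitin, the precursor of the protein tag ubiquitin, reached 4575 ± 1764 CPM, 7.27-fold above input. A C2H2 zinc-finger gene (TTHERM_00698680) was 10.3-fold higher and a serine/threonine kinase domain gene (TTHERM_00632930) was 4.51-fold higher. Leaving out the input of set 1 or of set 2 ended the calls of TTHERM_00713380 (adjusted p = 0.281 and 0.252), TTHERM_00077240 (0.117 and 0.125) and TTHERM_00632930 (0.197 and 0.206).

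The most depleted genes had no reads in both IPs. TTHERM_000956439, a hypothetical protein gene with 508 and 404 input reads in sets 1 and 2, was at least 509-fold lower in IP, set against a floor of 3 reads per library on the trimmed-mean scale (a mean of 0.0621 CPM in IP), and at least 304-fold lower on library totals (0.0790 CPM). Of the other 4, TTHERM_01336330, TTHERM_000635769 and TTHERM_00953990 are annotated as translation initiation factor eIF-5A family genes, and were at least 426-fold, 345-fold and 326-fold lower. Their ORFs span 1987, 6428 and 3263 bp, and the annotation was not checked. TTHERM_000617818, a putative transmembrane protein gene, was at least 290-fold lower. These bounds, and those of other features without IP reads, cover counting error only. The spread between the IPs was far larger: of 15566 ORFs with at least 200 reads in the IP of set 2, 787 had 0 in that of set 1. The true fold may therefore be smaller than a bound.

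Over all genes, 3651 were higher and 4556 lower in IP of 25359 tested, and the remaining ones did not pass the threshold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05). The median gene lay at a log2 fold change of −0.14, and at −0.59 with the block, −0.93 with DESeq2, −0.04 and −0.02 without the input of set 1 or 2, −0.83 without the IP of set 2 and, on the other side of 0, 0.13 without the IP of set 1. Of the lower genes, 2621 had no reads in both IPs. With the set as a block, 4234 genes were higher and 2028 lower. The split depended on the scaling, since enriched calls were 44.5% of all calls here, 61.5% with library totals in place of trimmed-mean factors (6074 higher and 3806 lower), 33.3% with factors from ORFs alone (2433 and 4876) and 28.3% with DESeq2 (2438 and 6181). Library totals moved the median log2 fold change to 0.76, so a gene counts as enriched here relative to the trimmed-mean scale. Leaving out 1 library gave 2159 higher and 1275 lower without the input of set 1, 2249 and 1284 without that of set 2, 7680 and 7888 without the IP of set 1, and 6846 and 11927 without that of set 2.

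The tagged gene itself was thinly covered. MED31 (TTHERM_00355460, scf_8254697, bases 1577958 to 1578652) had 15 and 26 reads in the inputs and 0 and 54 reads in the IPs of sets 1 and 2. Its log2 fold change was −1.82 (SE 2.12), which did not pass the threshold (adjusted p = 0.597). The log2 fold change was −0.67 without the IP of set 1. Without the IP of set 2, where no IP read is left, it passed as lower in IP (adjusted p = 0.00140). Of the 8 tested genes listed under Mediator and RNA polymerase II, 2 were higher, 2 lower and 4 did not pass (camera adjusted p = 0.979).

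Lists of genes drawn up from product names were compared with the other genes. With its preset correlation camera called 6 lists higher in IP and 3 lower, and with an estimated correlation it called 0, the smallest adjusted p being 0.319. The latter test has only 2 residual degrees of freedom, so a lost call does not by itself show correlation within a list. For ABC transporters the estimated correlation of −0.00389 was below the preset 0.01, yet camera's unadjusted p rose from 3.78e-07 to 0.0145. The fry test asks whether the members of a list change, rather than whether they change more than other genes. By fry the 9 lists called at the preset correlation passed too (adjusted p up to 0.0492). Lists that camera did not call also passed fry, such as Mediator and RNA polymerase II (adjusted p = 0.0408). Passing fry therefore does not restore the calls lost with an estimated correlation. Among leishmanolysin genes, which code for surface metalloproteases, 32 of 61 were higher in IP and 1 was lower (adjusted over the list alone, 38 and 2). TTHERM_00721820 went from 4.75 ± 0.502 CPM in input to 34.4 ± 14.6 in IP (SD, n = 2), and TTHERM_00147520 was 6.81-fold higher. The lower one, TTHERM_00289580, had 19 and 29 input reads and none in both IPs, at least 26.8-fold lower, a call that the block ended (adjusted p = 0.265), as did leaving out the input of set 1 or of set 2 (0.516 each). The list was higher than other genes by camera with its preset correlation (adjusted p = 1.55e-07) but not with an estimated correlation (adjusted p = 0.413).

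Of 163 tested genes for ABC transporters, which use ATP to move substrates across membranes, 62 were higher, 6 lower and 95 did not pass (67 higher and 6 lower adjusted over the list alone). The median log2 fold change was 1.10, and 0.48 with DESeq2 or 1.94 with library totals. The largest absolute changes in the list were of lower members, TTHERM_00992670, TTHERM_000561599 and TTHERM_000717638, which had no reads in both IPs and were at least 73.1-fold, 36.8-fold and 30.2-fold lower. The block ended those 3 calls (adjusted p = 0.0744, 0.233 and 0.253), and so did leaving out the input of set 1 (0.463, 0.516 and 0.516) or of set 2 (0.318, 0.505 and 0.516). Camera gave an adjusted p of 4.16e-06 for the list, and an adjusted p of 0.319 with an estimated correlation.

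Of 102 tested genes for chromatin-modifying proteins, 33 were higher and 3 lower (34 and 5 adjusted over the list alone). THD12 (TTHERM_01018450), a member of the SIR2 family of deacetylases, was 21.8-fold higher, at 51.4 ± 6.71 CPM in IP (SD, n = 2). Lower members were a PHD finger gene (TTHERM_00071060), with 106 and 121 input reads against 0 and 6 IP reads, and a SAP30 Sin3-binding gene (TTHERM_00392980), with 22 and 33 against 0 and 2. The call of TTHERM_00071060 was lost with library totals (adjusted p = 0.0745) and without the input of set 1 or 2 (adjusted p = 0.260 and 0.370). The call of TTHERM_00392980 was lost with library totals (0.0530), factors from ORFs alone (0.0514), no low-count filter (0.0529) or features adjusted together (0.0575), as well as with the block (adjusted p = 0.340) and without the input of set 1 or 2 (0.652 and 0.700). Camera gave the list an adjusted p of 0.000911, and an adjusted p of 0.367 with an estimated correlation.

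Papain-family and other cysteine proteases had 48 of 181 members higher and 24 lower (55 and 31 adjusted over the list alone). The list takes in the 56 tested genes named calpain family cysteine protease, of which 11 were higher and 1 lower. CTH105 (TTHERM_00486630), CTH63 (TTHERM_01359480) and GIP1 (TTHERM_00439250) were 10.3-fold, 9.75-fold and 9.38-fold higher, and the log2 fold change of CTH63 fell from 3.28 to 2.66 without the IP of set 1. Proteasome subunit genes had 10 of 31 higher and 1 lower (the same counts adjusted over the list alone), with PRE3 (TTHERM_00030440) 12.9-fold, PRE7 (TTHERM_00470650) 9.01-fold and RPN1 (TTHERM_00339610) 7.65-fold higher. The log2 fold change of PRE7 fell from 3.17 to 2.36 without the IP of set 1, and that of RPN1 rose from 2.93 to 3.60 without the input of set 1. Camera gave adjusted p of 0.00334 for the proteases and 0.0253 for the proteasome, and adjusted p of 0.367 and 0.413 with an estimated correlation. Without the IP of set 1 the proteasome call was lost (adjusted p = 0.128).

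Among genes for ciliary motors and intraflagellar transport, which move and build cilia, 30 of 111 were higher and 12 lower (30 and 13 adjusted over the list alone). Its largest absolute changes were an outer dynein arm gene (TTHERM_00455280), a dynein heavy chain gene (TTHERM_000919539) and an infraciliary-lattice centrin gene (TTHERM_00398080), each without reads in both IPs and at least 48.7-fold, 43.0-fold and 31.2-fold lower. The centrin gene entered the list through the word infraciliary in its name and need not code for a ciliary motor or transport protein. From the input of set 1 alone the bound of TTHERM_00455280 is 30.0-fold. Those 3 calls were lost with the block (adjusted p = 0.190, 0.212 and 0.250), without the input of set 1 (0.426, 0.512 and 0.519) and without that of set 2 (0.515, 0.494 and 0.514). Camera called the list higher (adjusted p = 0.00334), with an adjusted p of 0.367 with an estimated correlation.

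Of 113 tested genes for cytosolic ribosomal proteins, 63 were lower, 5 higher and 45 did not pass (64 lower and 10 higher adjusted over the list alone). The median log2 fold change was −1.65, and −2.22 with DESeq2 or −0.89 with library totals. The gene for 60S ribosomal protein L18 (TTHERM_000338239) went from 368 ± 14.2 CPM in input to 26.7 ± 11.0 in IP (SD, n = 2). Ribosomal protein L28 (TTHERM_00140980) and a ubiquitin/S27a fusion (TTHERM_000473360) had no reads in both IPs and were at least 21.3-fold and 21.2-fold lower, calls that the block ended (adjusted p = 0.286 for each). Their bounds are 9.996-fold and 32.2-fold from the input of set 1 alone, and 32.6-fold and 10.1-fold from that of set 2. Without the input of set 1 the call of TTHERM_00140980 was lost (adjusted p = 0.516), as was that of TTHERM_000473360 without the input of set 2 (0.515). These genes stood high in both inputs, with a median density of 73.4 CPM per kb against 2.04 for all ORFs. Their median IP density of 23.3 CPM per kb was also above the 1.99 of all ORFs, so lower here means relative to input. Without the 70 members at 5 times the median input density or above, a choice made after the data were seen, the other 43 had a median log2 fold change of 1.49, but a limit on input, the denominator of the ratio, itself raises the ratios that are left. Camera called the whole list lower (adjusted p = 0.00920), with an adjusted p of 0.640 with an estimated correlation, and without the IP of set 2 the call was lost (adjusted p = 0.107).

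The list of ion channel and cyclic nucleotide-binding genes, not all of which need code for channels, had 225 of 930 members lower and 41 higher (221 and 37 adjusted over the list alone). Of the lower members 201 were among the 632 tested genes named cyclic nucleotide-binding domain protein, while the 234 named cation channel family protein had 17 lower and 13 higher (camera adjusted p = 0.407 over families formed after the data were seen, and 0.867 with an estimated correlation). The cyclic nucleotide-binding gene TTHERM_001415159 was at least 262-fold lower, and the cation channel genes TTHERM_00717630 and TTHERM_00532410 were at least 81.0-fold and 80.3-fold lower. Protein kinase genes had 344 of 1274 lower and 155 higher (358 and 168 adjusted over the list alone). Among them TTHERM_001257658, TTHERM_00227670 and TTHERM_00321580 were at least 171-fold, 117-fold and 115-fold lower. The median log2 fold change of the list with ion channels was −1.06, and −1.73 with DESeq2 or −0.119 with library totals. That of kinases was −1.01, and −1.65 with DESeq2 or −0.0868 with library totals. Without the input of set 1 the calls of TTHERM_00717630, TTHERM_00532410, TTHERM_00227670 and TTHERM_00321580 were lost (adjusted p = 0.313, 0.417, 0.148 and 0.128), and likewise without that of set 2 (0.395, 0.286, 0.148 and 0.199). Camera gave adjusted p of 0.00334 for the list with ion channels and 0.0304 for kinases, with an adjusted p of 0.640 for each with an estimated correlation. The kinase call was lost without the IP of set 2 (adjusted p = 0.0657). Both calls ended when ORFs dense in input, a choice made after the data were seen, were left out of the lists (adjusted p = 0.187 for each) or of the lists and the other genes (0.0824 for each).

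The other lists were not called by camera, although by fry translation factors (adjusted p = 0.0138), DNA replication (0.0393), Mediator and RNA polymerase II (0.0408) and heat shock proteins (0.0492) passed. Surface antigen genes had 70 of 162 members lower and 21 higher (73 and 29 adjusted over the list alone; adjusted p = 0.355, and 0.981 with an estimated correlation). For 115 of the 162, input was dense, and the 47 others lay higher than other genes when dense ORFs were left out throughout, a choice made after the data were seen (adjusted p = 0.00301, and 0.3004 with an estimated correlation), with the same caution about the denominator. Glycolysis and citric acid cycle genes had 20 of 51 higher and 9 lower (21 and 9 adjusted over the list alone; adjusted p = 0.0621, and 0.866 with an estimated correlation), and passed with the block at the preset correlation (adjusted p = 0.0445). Oxidative phosphorylation had 6 of 41 higher and 9 lower (8 and 9 adjusted over the list alone; adjusted p = 0.542, and 0.726 with an estimated correlation). Translation factors had 24 of 121 higher and 45 lower (27 and 50; adjusted p = 0.205, and 0.625 with an estimated correlation). Of the lower members in that list, 35 were among the 45 tested genes named eIF-5A family, of which 0 were higher. The lower count thus comes mostly from 1 family, formed after the data were seen. Product names were not checked, so the members of that family need not all code for initiation factors. At the preset correlation, without the IP of set 1 that list was called lower (adjusted p = 0.0326), as were surface antigens (adjusted p = 0.0396). Without the IP of set 2 glycolysis was called higher (adjusted p = 0.00684).

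DNA replication genes had 8 of 35 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0646), and aminoacyl-tRNA synthetases had 10 of 37 higher and 3 lower (also the same; adjusted p = 0.473). Meiosis and conjugation genes, whose programme belongs to another life stage, had 9 of 27 higher and 5 lower (adjusted p = 0.236). Core and linker histones had 0 of 16 higher and 4 lower (0 and 3 adjusted over the list alone; adjusted p = 0.853). Heat shock proteins and chaperonins had 10 of 40 higher and 12 lower (11 and 14; adjusted p = 0.950), tubulins and actin 3 of 23 and 1 (1 and 1; adjusted p = 0.784), and ubiquitin 4 of 34 and 5 (adjusted p = 0.947). Dense-core granule proteins, which are secreted on stimulation, had 3 of 12 higher and 3 lower (adjusted p = 0.856). The list of mitochondrial ribosomal proteins matched 0 genes by name.

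**Figure D1:**
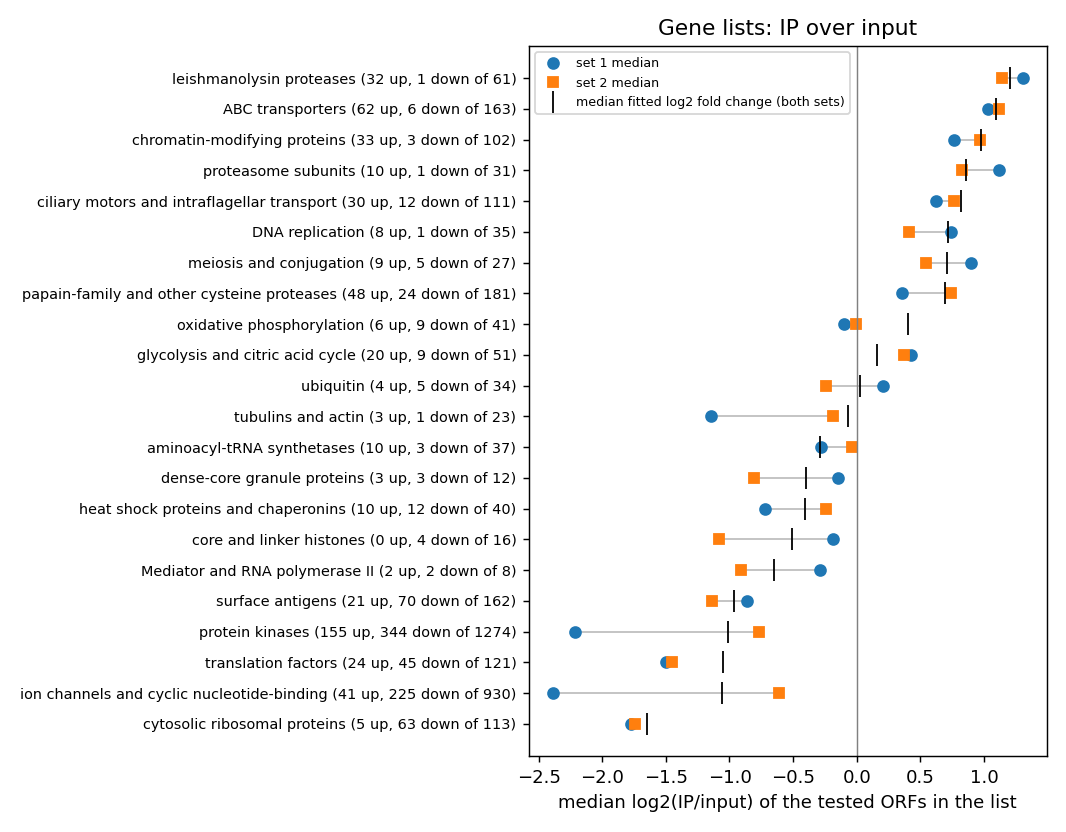
Median log2 IP/input ratio of the tested ORFs of each gene list (x axis), in set 1 (circles), in set 2 (squares) and as fitted over both sets (bars), with the number of members higher and lower in IP beside each list. Leishmanolysin proteases lie highest, at a fitted median of 1.21, and cytosolic ribosomal proteins lowest, at −1.65.

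Reads in input were unevenly spread over genes. Of the 26996 ORFs, 2569 (9.52%) had at least 5 times the median density in both inputs, and they held 85.7% and 85.0% of the ORF reads in the inputs of sets 1 and 2. The median log2 IP/input ratio was highest at middle input density, at 0.90 in set 1 and 0.85 in set 2 for the 2848 ORFs at 4 to 10 CPM per kb. It was lower at both ends: −5.07 and −2.78 for the 3057 ORFs at up to 1 CPM per kb, −1.81 and −0.25 for the 10113 at 1 to 2, and −1.82 and −2.47 for the 894 at over 100. Input is the denominator of the ratio, so chance errors in input push ratios down where input is high and up where it is low. That effect runs against the low ratios at up to 1 CPM per kb. There 72.5% and 47.0% of ORFs had no IP reads in sets 1 and 2, against 0% in both at over 100 CPM per kb. Short ORFs of up to 500 bp had medians of −4.18 and −2.49, and 61.1% and 45.3% of them had no IP reads in sets 1 and 2. In ORFs of over 4000 bp the medians were −0.17 and 0.16. These are medians per set without a test.

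**Figure D2:**
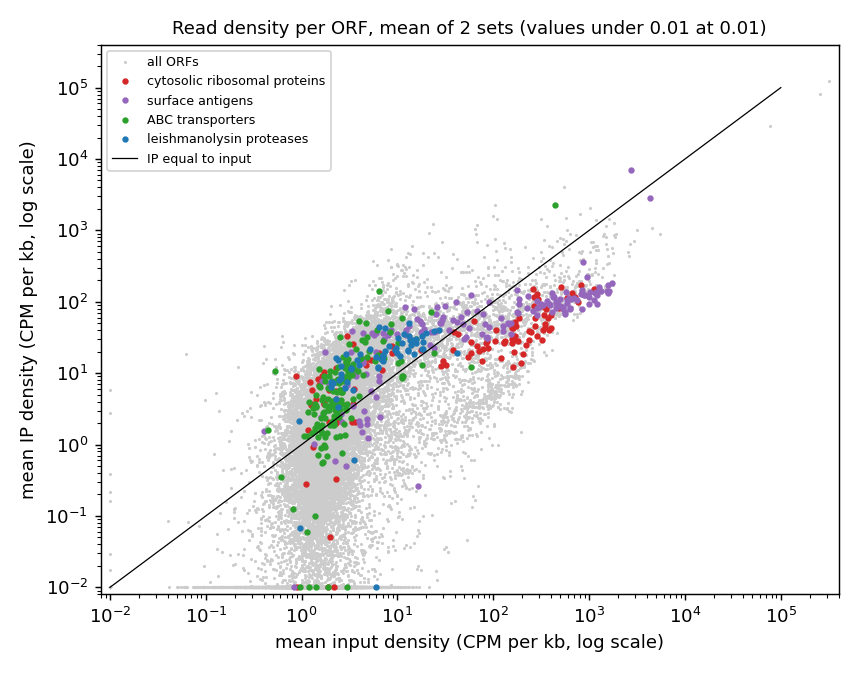
Mean IP density against mean input density per ORF, in CPM per kb on log axes (mean of the 2 sets, values under 0.01 drawn at 0.01), with 4 gene lists coloured and a line where IP equals input. Cytosolic ribosomal protein genes have a median of 73.4 CPM per kb in input and 23.3 in IP, and ABC transporter genes have 2.37 and 5.45.

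More intergenic regions were lower in IP than higher. Of 18959 tested, 228 were higher and 6075 lower, and the median log2 fold change was −2.80, against −0.14 for ORFs. The intergenic median was −1.61 with library totals, −1.20 with factors from intergenic regions alone, −3.21 with DESeq2 and −4.17 with the block, −2.07 and −2.06 without the input of set 1 or 2, −2.65 without the IP of set 1 and −7.09 without that of set 2. The 5 most enriched regions were 71.4-fold, 52.5-fold, 34.6-fold, 33.3-fold and 24.6-fold higher in IP, and the first of them had 52 and 52 input reads and 10911 and 15190 IP reads in sets 1 and 2 (adjusted p = 0.0139). The call of the third was lost without the IP of set 1 or of set 2 (adjusted p = 0.169 and 0.127) and without a low-count filter (0.0555), and its log2 fold change of 5.11 was 6.01 without the input of set 1. The 3 most depleted had no reads in both IPs and were at least 789-fold, 329-fold and 323-fold lower. In 8 bins of matched input count, the ORF median exceeded the intergenic median in every bin of both sets. The weighted mean difference on the log2 scale was 3.78 in set 1 (0.76 to 6.70 over bins) and 2.45 in set 2 (2.27 to 3.29). Of all intergenic regions, 70.7% and 43.8% had no reads in the IPs of sets 1 and 2, against 4.84% and 6.39% in the inputs. The ratio of a region without IP reads rests on the pseudocount, so the size of these differences depends in part on it.

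The positions of these regions are not given, because counts and region names were out of step in the intergenic tables. The names of 4920 rows (17.7%) lay outside scaffold order. Disorder alone does not show this, since 6876 ORF names (25.5%) did too, with ORF length and input count related there (Spearman rho 0.679). In the intergenic rows out of order, region length and input count were unrelated (Spearman rho 0.00118, 95% bootstrap interval −0.0265 to 0.0306, across regions), against 0.573 in the rows in order and 0.666 over all ORFs. The 506 regions at least 1.5-fold higher in both sets fell in IP/input ratio with row number (Spearman rho −0.882), while the 5949 ORFs that met the same rule showed a rho of −0.0222. Both inputs still matched each other row by row in the out-of-order rows (rho 0.807), so the sets shared a row order. That match does not show that the input and IP counts of a row belong to the same region, which was not checked. Counts within a row were compared on that assumption, but not by place or length. With the set as a block, 151 regions were higher and 1221 lower. With factors from intergenic regions alone, enriched calls were 19.2% of all calls (466 higher and 1964 lower) against 3.62%. Leaving out 1 library gave 78 higher and 719 lower without the input of set 1, 80 and 732 without that of set 2, 1950 and 11723 without the IP of set 1, and 1546 and 15427 without that of set 2.

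The planned comparison of each ORF with the regions beside it rests on those names. Across 13125 ORFs with enough reads, Spearman's rho between the log2 ratio of the ORF and that of its named flanks was 0.135 in set 1 and 0.191 in set 2. Limited to flanks with names in order, a choice made after the data were seen, rho was 0.175 and 0.240 over 8938 ORFs. Names in order need not be right either: in such rows with reads in both IPs region length and input count had a rho of 0.234, against 0.662 in those without IP reads and 0.515 in the ORFs in order with reads in both IPs. Genes are not independent replicates, and no test was made.

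Taken set by set, enrichment was shared beyond independent lists. Of 20050 ORFs with at least 20 reads in each input, 7558 were at least 1.5-fold higher in IP in set 1 and 8176 in set 2. They shared 5949 ORFs, against 3082 for independent lists of those sizes. Of 8862 intergenic regions, 877 and 900 met the rule and 506 were shared, against 89.1. The log2 ratios of the sets correlated across ORFs with Pearson's r 0.667 and Spearman's rho 0.739, and across intergenic regions with 0.533 and 0.509. Counting noise alone, simulated around shared levels per feature, gave a Pearson's r of 0.990 for ORFs and 0.979 for intergenic regions. The median absolute difference between sets was 1.03 and 1.69 on the log2 scale, against 0.170 and 0.332 with counting noise alone. The sets thus differed by much more than counting noise.

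**Figure D3:**
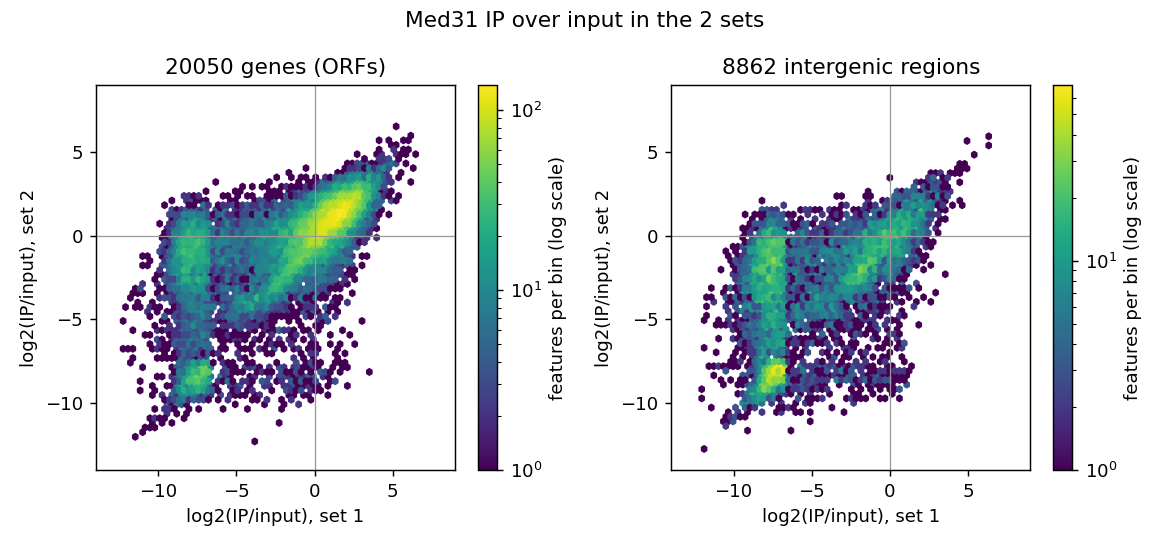
Log2 IP/input ratio in set 2 against set 1 for 20050 ORFs (left) and 8862 intergenic regions (right), both with at least 20 reads in each input, with colour for the number of features per bin on a log scale. ORFs lie along the diagonal with Pearson's r 0.667, and a column at the left holds features without reads in the IP of set 1.

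The share of counted reads that fell in ORFs was 68.7% and 68.6% in the inputs of sets 1 and 2 (exact 95% binomial intervals 68.7 to 68.7 and 68.6 to 68.6) and 78.0% and 80.3% in the IPs (77.9 to 78.0 and 80.3 to 80.3). The means were 68.7% ± 0.0981 in input and 79.1% ± 1.65 in IP (SD, n = 2 each). Both IPs lay above both inputs by more than the spread between replicates, and the difference of 10.5 percentage points had p = 0.333 in an exact 2-sided permutation test, the smallest p that 2 against 2 libraries allow. Without the 1% of features with most reads the difference was 15.7 percentage points. A pair of scaffolds of 1382 and 1006 bp held 32.7% and 32.5% of the counted reads in the inputs of sets 1 and 2, and 23.6% and 16.05% in the IPs. Genes without any reads were more frequent in IP, at 30.8% and 16.2% of ORFs in sets 1 and 2, than in input, at 0.678% and 0.996%.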

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

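Among these alternatives, those chosen only after the results were seen are the ones without the 2 densest scaffolds, without ORFs dense in input, and limited to regions with names in order. No direction of a named gene or region turned under any alternative that gave it a value. Enriched ORFs numbered 3651, and 6074 with library totals or 2433 with TMM over ORFs alone. Depleted ORFs numbered 4556, and 1847 with at least 50 reads in each input. Enriched intergenic regions numbered 228, and 466 with TMM over intergenic regions alone, 46 without a low-count filter and 137 with at least 50 input reads. Depleted ones numbered 6075, and 1874 with library totals, 1964 with their own TMM, 475 without a filter and 1308 with at least 50 input reads. The lower counts with at least 50 input reads come with fewer features tested (12635 ORFs and 3802 regions). The cause of the other changes was not tested.

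With the set as a block, pairing input and IP, 2028 ORFs were depleted in place of 4556, 151 intergenic regions were enriched in place of 228 and 1221 were depleted in place of 6075. Glycolysis passed with the block in camera at the preset correlation (adjusted p = 0.0445), while without the block an estimated correlation gave 0.866. The block changed no other call of a list. Of the named features 10 lost their call with the block, 2 with library totals, 2 without a low-count filter, 1 with TMM over its own kind of feature and 1 with ORFs and regions adjusted together. Of the depleted ORFs, 1631 were shared by both fits.

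Leaving out 1 library gave 2159 to 7680 enriched and 1275 to 11927 depleted ORFs, and 78 to 1950 enriched and 719 to 15427 depleted intergenic regions. The smaller counts came without the input of set 1, and the larger ones without the IP of set 1 (enriched) or of set 2 (depleted). With 1 library left in a group, that library is assumed to vary like the other group. Adjusted p over these 4 fits ranged from 0.00425 to 0.107 for ribosomal proteins, 0.00992 to 0.128 for the proteasome, 0.0259 to 0.0657 for kinases, 0.00684 to 0.333 for glycolysis, 0.0326 to 0.354 for translation factors and 0.0396 to 0.940 for surface antigens. The other lists kept their side of the threshold. Of the named features, 17 lost their call without the input of set 1 and 17 without that of set 2, 2 without the IP of set 1 and 2 without that of set 2, where MED31 gained one.

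With an estimated correlation, whose test has 2 residual degrees of freedom, none of the 9 lists called at the preset correlation was called. Adjusted p was 0.319 for ABC transporters, 0.367 for ciliary motors, papain-family proteases and chromatin-modifying proteins, 0.413 for leishmanolysin proteases and the proteasome, and 0.640 for ribosomal proteins, kinases and the list with ion channels and cyclic nucleotide-binding proteins (here ion channels). With library totals, glycolysis passed at the preset correlation (adjusted p = 0.0237), while on the main scaling an estimated correlation gave it 0.866. Without members dense in input, the direction was higher in IP for ribosomal proteins (adjusted p = 0.00278) and surface antigens (0.00129), glycolysis (0.000108) and oxidative phosphorylation (0.0205) passed, and kinases and ion channels did not (0.187 each). That limit is on the denominator of the ratio and raises the ratios left in a list, so these changes follow in part from its construction. With dense ORFs left out of the other genes as well, adjusted p was 0.00637, 0.00301, 0.000234, 0.0352 and 0.0824 (kinases and ion channels) in the same order and directions. With an estimated correlation besides, 0 lists were called: adjusted p was 0.3004 for ABC transporters, leishmanolysin and papain-family proteases, chromatin-modifying proteins, the proteasome, surface antigens, glycolysis and oxidative phosphorylation, 0.338 for ciliary motors, 0.346 for ribosomal proteins, 0.604 for kinases and 0.679 for ion channels.

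The 1.5-fold rule gave 506 intergenic regions in both sets, and 1149 without an input minimum, 251 with at least 50 input reads and 901 with library totals. For ORFs every alternative stayed within 1.5 times of 5949. Agreement between sets rose with depth, from r = 0.667 to 0.711 for ORFs and from 0.533 to 0.612 for intergenic regions with at least 50 input reads, and was 0.715 and 0.595 with a pseudocount of 5. The ORF share differed by 15.7 percentage points without the 1% of features with most reads, against 10.5. Spearman's rho of ORF and flanks was 0.169 and 0.281 in sets 1 and 2 with at least 50 input reads, and 0.175 and 0.240 with names in order. Leaving out the 2 densest scaffolds gave 3654 enriched and 4561 depleted ORFs. Depth limits how far depletion can be measured, since 2621 of the 4556 depleted ORFs had no IP reads and have only a lower bound, which covers counting error alone. The comparison by gene orientation was not run, as strand was not given.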

Other observations

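The tests of gene families, of counting noise, of the IP libraries and of the order of the intergenic tables were chosen only after the results were seen. Families were formed from the 37 product names carried by at least 40 ORFs. The eIF-5A family stood lowest: 35 of its 45 tested ORFs were lower in IP, 0 were higher, and the median log2 fold change was −5.81. Of 44 oxalate/formate antiporter ORFs, 38 were lower and 0 higher (median −4.18). These antiporter genes had a median input density of 92.1 CPM per kb and an IP density of 4.60. At the other end, 21 of 43 aldo/keto reductase ORFs were higher and 0 lower (median 2.09), and 42 of 86 lsd1-subclass zinc finger ORFs were higher and 2 lower (median 1.23). Camera called all 4 with its preset correlation (adjusted p = 5.65e-12, 9.26e-12, 1.80e-06 and 3.99e-07 in that order), and adjusted p was 0.361, 0.244, 0.244 and 0.244 with an estimated correlation. These medians kept their sign under each scaling tried.

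The kinases split by product name. ORFs called kinase domain protein had 319 of 818 members lower and 40 higher (median −2.47), while those called Serine/Threonine kinase domain protein had 81 of 315 higher and 11 lower (median 0.89). Camera gave adjusted p of 3.44e-09 and 4.30e-05, and adjusted p of 0.335 and 0.244 with an estimated correlation. MFS transporters had 51 of 167 higher and 23 lower (median 1.23), and cyclic nucleotide-binding proteins had 201 of 632 lower and 23 higher (median −1.53). The difference between families was not tested.

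Reads in the inputs were uneven between genes, although input is meant to sample the genome evenly. Counting noise is argued against, since 91.7% of the ORFs at 5 times the median input density in set 1 were so in set 2. More copies of DNA segments that span several ORFs are argued against for most dense ORFs, as ORFs beside a dense ORF had only 1.18 times the median density of all ORFs (95% bootstrap interval 1.14 to 1.21). However, 18.5% of the ORFs beside a dense ORF were dense themselves, against 9.52% of all ORFs. Extra copies of a single ORF or of a short scaffold would not show in this test and stay open. Reads shared by near-identical copies stay open without a genome sequence. A product name that at least 5 ORFs share was carried by 70.3% of dense ORFs, but the same share over all ORFs was not computed. Since hypothetical protein alone names 9789 of the 26996 ORFs, a shared name does not mark a copy. Transcript-derived reads and readier recovery of active chromatin may also contribute and cannot be told apart: the ratio of flank to ORF density in dense ORFs was 0.0946 times that in other ORFs, but flanks shuffled among ORFs gave 0.0408, so that test decides nothing.

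The IP libraries were patchy, with many genes at 0 in 1 or both of them. Low depth is argued against, because the smaller IP held 1.74 times the counts of the larger input. Amplification of few DNA molecules may contribute and stays open: the variance between IPs was 210 times the counting variance in the lowest count bin (7.49 in inputs). That multiple was 169, 165, 255 and 634 in the next 4 bins, so it did not rise over the lower 3 bins, as few molecules would give, but did in the upper ones, where few molecules alone would not raise it. From the lowest to the highest bin it rose 3.02-fold over a 46.9-fold rise in count, which decides neither way. Of the 15566 ORFs with at least 200 reads in the IP of set 2, 787 (5.06%) had 0 in that of set 1, against 16 of 11601 (0.138%) the other way round, so most such genes were missing from the IP of set 1. For the 3915 ORFs at 0 in both IPs, 2.90 times the number for independent lists, the biological reading stays open, because few molecules and short ORFs would give an excess as well.

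Counts and region names in the intergenic tables were out of step. A sort that moved whole rows is argued against, since region length and input count had a Spearman rho of 0.00118 in the rows with names out of order (n = 4920 regions), against 0.679 in the 6876 ORF rows out of order. A biological order that puts enriched ORFs and regions alike on the first scaffolds is argued against by the enriched ORFs, whose ratio had a rho of −0.0224 with position by scaffold number and start (95% bootstrap interval −0.0450 to 0.00381). An order of regions alone was not tested. The rho of −0.882 over 506 enriched regions is consistent with counts sorted apart from names when the tables were assembled, which is a hypothesis from the same rows. Coordinates of intergenic enrichment from these tables would need recounting from reads.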
